A study of Mus musculus with 8 samples.

How the data were processed

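RNA from Csk-deficient mouse embryonic fibroblasts with a doxycycline-inducible c-Src vector was measured at 0, 6, 24 and 72 h of induction, with 2 arrays per time and 8 arrays in all. Per the labels' protocols, RNA was extracted with Sepazol, total RNA was labelled with Cy3, and each sample was run in duplicate on a 1-colour 8x60K mouse array. Per the file headers, the scans were quantified with Feature Extraction 10.5.1.1 on the mm9 build, whereas the submitters' processing notes give version 10.7.3.1, and the difference was left open. The processed signal per spot is an intensity on a linear scale, per the file headers. The deposited value table holds the same intensity rounded to 3 significant digits, with a largest difference of 0.497%. All arrays lay on 1 slide and were scanned once, with replicate number following the slide column and time following the slide row.

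The processed signal of each spot was put on the log2 scale and the 75th percentile of the array's 59305 spots that are not controls was subtracted. That percentile lay between 370.3 and 393 and the median signal between 16.8 and 20.4 across arrays. Between 49.9% and 54.7% of spots were well above background, 0 were saturated and 146 to 208 were outlier spots. Spots of a probe were averaged. A probe was kept if it was well above background on every array of at least 1 time, which held for 28610 of 55681 probes. The probe with the highest mean signal stood for its gene, which gave 20840 genes, of which 7754 have names of clones or loci. Names were assigned to 26582 probes by RefSeq accession, 2602 by symbol and 492 by synonym, and 26005 kept the name in the file.

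Differences between times were tested with limma 3.58.1 in R 4.3.3, with 4 means fitted to 8 arrays (4 residual degrees of freedom, prior 1.7), and p-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The median standard error of a difference was 0.075 on the log2 scale. The SD between replicate arrays over 270 probes with several spots had a median of 0.039 to 0.059 per time, against 0.035 to 0.042 between spots of an array. All called genes had the same sign in each slide column, but a call at this threshold all but requires that, so it is no check of replication. Gene lists were tested with camera at a correlation of 0.01, and again with a correlation estimated from the data, and adjusted over 63 tests (21 lists with at least 5 tested genes and 3 comparisons with 0 h). With an estimated correlation, camera rests on the 4 residual degrees of freedom, so few lists can pass whatever their correlation. Failing that second test therefore does not by itself show that correlation between members made a call. The estimates ran from -0.026 for YAP/TEAD targets to 0.305 for the ATF4 list, with 0.188 for TGF-beta, 0.172 for glycolysis and 0.151 for G2/M. For lists with an estimate far above 0.01, the p-values at a correlation of 0.01 may be too small. The 25 lists were immediate early genes, ERK output, STAT3 targets, SRF and actin genes, YAP/TEAD targets, extracellular matrix, matrix proteases, G2/M, DNA replication, glycolysis, cholesterol synthesis, interferon response, NF-kB targets, ATF4 and amino acid response, p53 targets, TGF-beta targets, Src family and focal adhesion, oxidative phosphorylation, heat shock, and markers of fibroblasts, epithelium, macrophages, endothelium, skeletal muscle and adipocytes. Files were read with the packages data.table (1.17.8) and jsonlite (2.0.0), and figures drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

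The comparisons, lists, list tests and the rule for naming genes were fixed before the data were examined, as were all alternatives but 1, the Src family list without Src. The tests of explanations for single patterns were set later, 5 of them only after the result was seen. The rule names Src, Csk and Fer, the 10 largest rises and 10 largest falls at each time against 0 h, 5 and 5 for each step between later times, and up to 4 called members of each list past the threshold. Where a gene was not well above background on any array of a time, its fold was computed against the background limit and is given as at least that fold. That limit was the lowest signal well above background on each array, or the gene's own signal where higher. Such folds use the means of a time's arrays and depend on the limit chosen, so they are not strict lower limits. The method was tested on simulated data with the means of the 0 h arrays and the spread fitted over all 8 arrays. In each of 20 simulations, 50 genes were changed at 6 h for each fold. The method called 7.8% of genes changed 1.25-fold, 59.2% at 1.5-fold, 85.1% at 2-fold and 95.7% at 4-fold, and 0.04% of unchanged genes. In the simulations 20625 of 20840 genes were unchanged, whereas 17.5% of genes were called at 6 h in the data. These rates therefore need not carry over to the data. A list of 15 genes raised by 0.5 was called in 20 of 20 simulations and an unchanged list in 0 of 20. The noise was drawn independently for each gene, so these lists cannot show false calls that arise from correlation between members. Alternatives covered background correction, scaling, filtering, the choice of probe, the variance model, a block on replicate number, the list test, thresholds and leaving out each array. MicroRNA target sites were not analysed here, since that needs sequences of untranslated regions.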

Results

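Gene expression was measured over a time course of c-Src induction in mouse embryonic fibroblasts that lack Csk, the kinase that phosphorylates and restrains Src family kinases. The cells carried a c-Src vector switched on by doxycycline (1 µg/ml), and total RNA was taken after 0, 6, 24 and 72 h. There were 2 arrays for each of the 4 times, 8 in all, each a 1-colour whole-genome oligonucleotide array with 59305 spots that are not controls. Between 49.9% and 54.7% of these spots were well above background on an array and no spot was saturated. Replicate arrays of a time correlated across genes with r between 0.9963 and 0.9974. The labels say that each sample was run in duplicate and not that the duplicates came from separate cultures, so the p-values measure the spread between these arrays, which may be technical. The cells of every induced array had received doxycycline and may have had a longer culture, and time also followed the row on the slide. The effects of these cannot be told apart from that of c-Src. The question of each comparison was which transcripts differ as induction goes on.

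Src itself rose 26.9-fold by 6 h (log2 difference 4.75 ± 0.06 SE, adjusted p = 1.44e-05 by limma) and stood 23.8-fold above 0 h at 24 h (4.57 ± 0.06) and 19.6-fold above it at 72 h (4.29 ± 0.06). Under another background correction, normexp, the log2 differences were 4.28, 4.12 and 3.85, or 19-fold, 17-fold and 14-fold. The array holds 1 Src probe, at chromosome 2, 157293336 to 157294267 on the mm9 build, and it was well above background on all 8 arrays. Src fell by 0.28 on the log2 scale between 24 h and 72 h (adjusted p = 0.0277), a call lost in 9 of 19 alternative settings (adjusted p up to 0.128), while its 24 h minus 6 h difference of -0.18 did not pass the test (adjusted p = 0.0846). The Csk probe, at chromosome 9, 57474734 to 57474793 was not well above background on any of the 8 arrays, whose labels give the genotype as Csk-deficient. Fer, a cytoplasmic tyrosine kinase, has 3 probes at chromosome 17 between 64488309 and 64488690. Its brightest probe differed by 0.19 ± 0.09 at 6 h (adjusted p = 0.231). It rose 1.72-fold at both 24 h (0.78 ± 0.09, adjusted p = 0.00182) and 72 h (0.79 ± 0.09, adjusted p = 0.00117). The other Fer probes differed by 0.59 and 0.73 at 24 h and by 0.66 and 0.55 at 72 h.

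**Figure D1:**
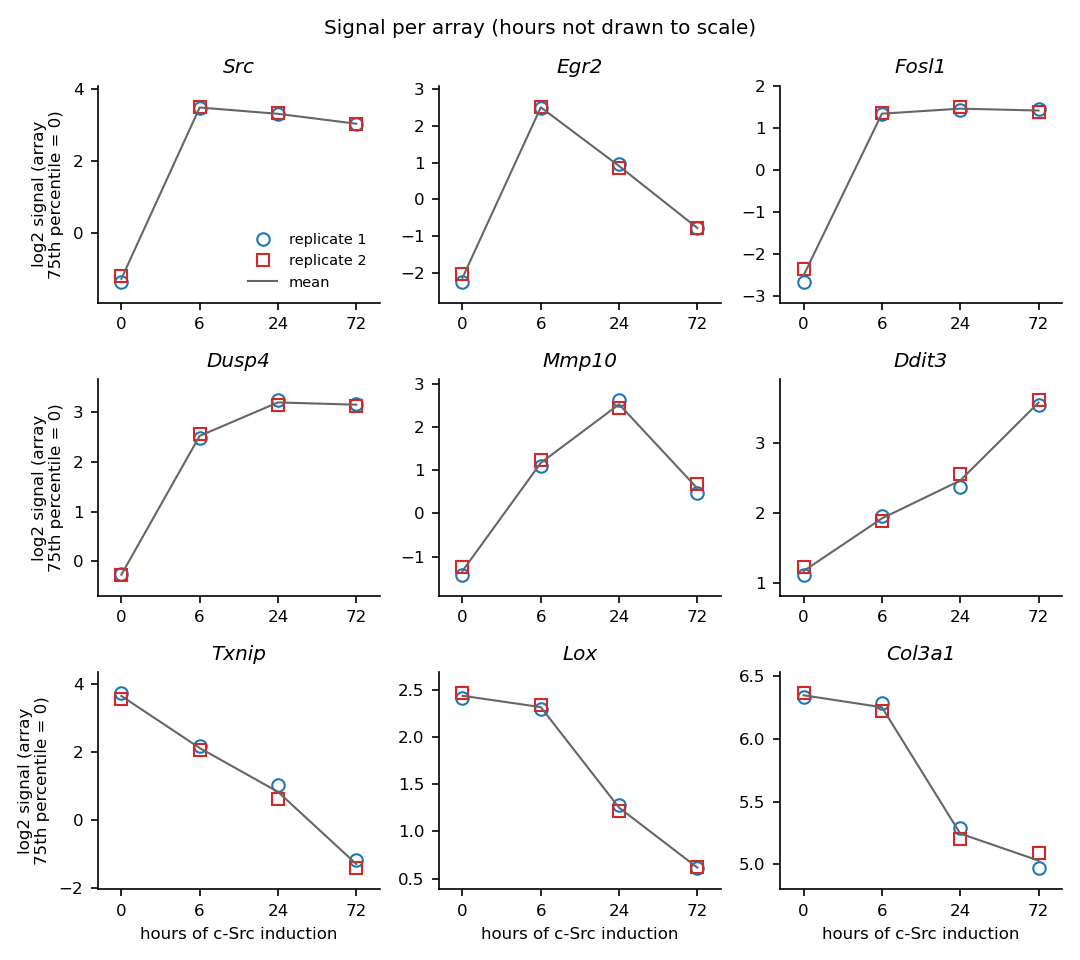
Log2 signal relative to the array's 75th percentile (vertical axis) for 9 genes at 0, 6, 24 and 72 h of induction (horizontal axis, not to scale), with 1 symbol per array and a line through the means. Src rose by 4.75 at 6 h and stayed high, Egr2 rose by 4.64 and then fell back, Ddit3 climbed to 2.40 above 0 h, and Txnip, Lox and Col3a1 were lower at 24 h and 72 h than at 0 h.

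At 6 h transcription factor genes that respond within hours to growth factors were raised, Egr2 and Fosl1 among them. With them rose genes of secreted products, namely the protease inhibitor gene Serpinb2 and the growth factor genes Csf2 and Csf3 of white blood cell lineages. Genes of the cornified envelope, the protein shell of skin cells, were also among the largest rises, and Txnip was among the largest falls. The transcription factor genes Egr2 and Fosl1 rose by 4.64 ± 0.08 and 3.85 ± 0.10 on the log2 scale, and Ptgs2, the inducible cyclooxygenase, rose 10.3-fold (3.36 ± 0.09). Serpinb2, an inhibitor of plasminogen activators, and the colony-stimulating factor genes Csf2 and Csf3 were not well above background at 0 h. They rose at least 36.5-fold, 9.28-fold and 4.6-fold. Ivl, which encodes involucrin of the epidermal cornified envelope, rose 9.90-fold (3.31 ± 0.19). Sprr2h, from the small proline-rich family of the same structure, rose at least 8.69-fold and the prolactin family gene Prl2c5 10.8-fold (3.43 ± 0.08). The Sprr2 and Prl2c families hold near-identical copies, so which copy these probes read is uncertain. These sizes hold for the processed signal. Normexp background correction, which adds an offset and so shrinks the differences of dim probes, kept every one of these calls with smaller values. It gave 3.83 for Egr2, 3.19 for Serpinb2, 3.01 for Fosl1, 1.95 for Ptgs2, 1.83 for Prl2c5, 1.81 for Ivl, 1.52 for Csf2, 1.24 for Sprr2h and 1.01 for Csf3. Among the falls, Txnip, an arrestin that restrains glucose uptake, fell by 1.52 ± 0.15 on the log2 scale, Fry, a cytoskeletal regulator, by 1.43 ± 0.17, Grrp1 by 1.36 ± 0.17, Bspry by 1.21 ± 0.14 and the kinase gene Dclk3 by 1.17 ± 0.07. Fry, Grrp1 and Bspry were well above background on 1 of the 2 arrays at 6 h, and normexp background correction gave -0.33, -0.29 and -0.22 for them, the last no longer called (adjusted p = 0.0518). For 5 further genes the 6 h level was not well above background. The ubiquitin ligase gene Trim40 (adjusted p = 0.00272) was at least 1.98-fold lower. The epidermal caspase gene Casp14 (adjusted p = 0.0406, lost in 11 of 18 alternative settings) was at least 2.80-fold lower. The aminopeptidase gene Xpnpep2 was at least 2.32-fold lower, the sulfotransferase gene Sult6b1 at least 2.03-fold and Tada2b, a subunit of histone acetyltransferase complexes, at least 1.42-fold. Tada2b was well above background on 1 of the 2 arrays at 0 h. Of 18 alternative settings, 6 each ended the calls of Xpnpep2 (adjusted p up to 0.198) and Sult6b1 (up to 0.113) and 2 that of Tada2b (up to 0.395). Normexp background correction gave -0.35 for Trim40, -0.28 for Casp14, -0.26 for Xpnpep2, -0.21 for Sult6b1 and -0.11 for Tada2b, and of these only Trim40 kept its call. A common floor for all arrays gave -0.65 for Trim40, -1.2 for Casp14, -0.97 for Xpnpep2, -0.69 for Sult6b1 and -0.17 for Tada2b. Each of these is smaller than the fold given above as at least reached.

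All 15 tested immediate early genes rose at 6 h (also 15 adjusted over the list alone; median log2 difference 1.54; camera adjusted p = 4.40e-17), among them Egr1 (8.94-fold) and Fos (6.00-fold, 1.85 on the log2 scale under normexp). Of the 15 genes of ERK pathway output and feedback, 13 rose (14 adjusted over the list alone; median 1.33), including the MAP kinase phosphatase genes Dusp4 (6.88-fold) and Dusp6 (6.57-fold) and the Ets factor gene Etv5 (5.54-fold). Of 14 NF-kB targets and cytokines, 13 rose (14 adjusted over the list alone; median 1.44), with the chemokine genes Cxcl1 up 4.85-fold and Ccl7 3.74-fold and the adhesion molecule gene Vcam1 4.49-fold. SRF and actin cytoskeleton genes rose in 11 of 17 cases (12 adjusted over the list alone; median 0.51), including smooth muscle actin Acta2 (2.88-fold), Srf itself (2.60-fold), the focal adhesion adaptor gene Tgfb1i1 (3.01-fold) and the calponin gene Cnn2 (2.33-fold). With a correlation estimated from the residuals, the adjusted p of each of these 4 lists was 0.0723, so none of the 4 calls held.

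STAT3 targets rose at 6 h in 9 of 12 cases and fell in 1 (the same counts adjusted over the list alone), with the cytokine genes Il6 (2.92-fold, 0.95 on the log2 scale under normexp) and Lif (2.29-fold), Junb (3.27-fold) and Bcl3 (1.83-fold) leading. Among 15 matrix proteases and inhibitors, 8 rose and 2 fell (10 and 2 adjusted over the list alone). The stromelysin genes Mmp10 and Mmp3 rose 5.64-fold and 3.06-fold (0.89 on the log2 scale under normexp for Mmp3) and the urokinase receptor gene Plaur 2.70-fold. Of 16 p53 targets, 8 rose and 2 fell (9 and 2 adjusted over the list alone), led by the cell cycle inhibitor gene Cdkn1a (3.21-fold), Plk2 (2.67-fold), the death receptor gene Fas (1.96-fold) and Aen (1.83-fold). Fibroblast and mesenchymal markers rose in 6 of 12 cases (7 rose and 1 fell adjusted over the list alone), including the transcription factor genes Snai1, Zeb2 (both 1.52-fold), Zeb1 (1.36-fold) and Twist1 (1.34-fold). Besides Src, the list of Src family kinases and focal adhesion genes, with 6 of 18 up and 1 down (the same counts adjusted over the list alone), held Bcar1 (1.51-fold), an adaptor and Src substrate, and the fibronectin receptor subunit Itga5 (1.47-fold), while tensin Tns3 fell by 0.66 ± 0.08. Without Src, a test chosen after the data were seen, the other 17 genes still passed (5 up and 1 down, median 0.12, adjusted p = 0.0195), but not with an estimated correlation (0.219). The 5 full lists of this paragraph had an adjusted p of 0.152 each with an estimated correlation.

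Glycolysis genes rose in 7 of 16 cases at 6 h (11 adjusted over the list alone), with hexokinase Hk2 (2.61-fold), glucose transporter Slc2a1 (1.93-fold), lactate transporter Slc16a3 (1.53-fold) and Pgam1 (1.29-fold) in front and an adjusted p of 0.193 with an estimated correlation. ATF4 and amino acid response genes rose in 7 of 15 cases (8 adjusted over the list alone), led by Ddit3 and Slc7a11 (both 1.68-fold), Ddit4 (1.39-fold) and Atf4 (1.28-fold), with an adjusted p of 0.259 with an estimated correlation. Heat shock genes rose in 3 of 8 cases (5 adjusted over the list alone), namely Hsph1 (1.26-fold), Hspd1 (1.21-fold) and Dnajb1 (1.14-fold). The same estimate gave an adjusted p of 0.194 for heat shock genes and for DNA replication genes, of which 4 of 16 rose (5 adjusted over the list alone): Ccne1 (1.30-fold), Rrm2 (1.16-fold), Cdc6 (1.14-fold) and Mcm4 (1.13-fold). The median of the DNA replication genes was 0.05 and turned to -0.01 under quantile normalization, and a second Cdc6 probe gave -0.10. Of 21 alternative settings, 14 ended the call of the DNA replication list (adjusted p up to 0.668), 5 that of the heat shock list and 3 each those of the TGF-beta and G2/M lists. TGF-beta targets rose in 5 of 11 cases (5 rose and 1 fell adjusted over the list alone), including Bhlhe40 (3.31-fold), Tgif1 (1.42-fold) and Skil (1.31-fold). Of 16 G2/M cell cycle genes none rose and 2 fell (1 adjusted over the list alone), the mitotic kinase gene Aurkb by 0.31 ± 0.06 and the kinetochore gene Cenpf by 0.43 ± 0.11. The adjusted p with an estimated correlation was 0.315 for both TGF-beta and G2/M lists. Of 19 alternative settings, 14 ended the call of Cdc6, 12 that of Mcm4, 11 Cenpf, 10 Rrm2, 10 Dnajb1, 9 Atf4, 8 Hspd1, 7 Aurkb and 7 Pgam1. They ended those of Slc7a11 and Itga5 in 4 settings each and of Slc16a3, Tgif1 and Skil in 3 each.

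In numbers, 2151 of 20840 tested genes were higher and 1504 lower at 6 h than at 0 h (17.5% called, 58.9% of the calls higher), and 181 of the higher and 45 of the lower genes differed at least 2-fold. The arrays of the 2 times did not overlap for 62.7% of genes, against 33.3% by chance. The split of calls depended on scaling, with 1754 higher and 526 lower under median scaling (76.9% higher) and 1804 and 2040 under quantile normalization (46.9% higher). The counts also fell to 986, 1065, 1023 and 801 higher and to 628, 503, 498 and 414 lower without 0 h replicate 1, 0 h replicate 2, 6 h replicate 1 and 6 h replicate 2 in turn. They fell to 978 lower without either 72 h array.

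By 24 h the prolactin family genes Prl2c5 and Prl2c1, whose products are secreted, were among the largest rises, and Serpinb2 and Sprr2h were still far above their 0 h level. Axin2, a feedback inhibitor of Wnt signalling, and the growth factor gene Fgf9 were among the largest falls. The collagen gene Col3a1 and the interferon-induced gene Gbp2 fell, while the hexokinase gene Hk2 and the stress factor gene Ddit3 rose. The prolactin family genes Prl2c5 (158.5-fold, log2 difference 7.31 ± 0.08) and Prl2c1 (at least 76.6-fold) rose, as did Sprr2h (at least 51.2-fold) and Serpinb2 (at least 36.7-fold), with the copies of the Prl2c and Sprr2 families again uncertain. Normexp background correction kept these 4 calls with log2 differences of 5.27, 4.17, 3.25 and 3.21. Csf2 was higher by at least 3.40 on the log2 scale, Evi2a at least 10.1-fold, the dynactin-associated gene Dynap at least 6.95-fold and urate oxidase Uox at least 5.34-fold. Probes of Efcab1 (at least 13.4-fold) and Rpl10l (at least 10.6-fold) were bright on both 24 h arrays and on no other, and these features lie 2 rows apart on the array. With normexp the values were 1.95 for Efcab1, 1.79 for Rpl10l, 1.64 for Csf2, 1.51 for Evi2a and 1.17 for Uox, and Dynap rose 2.4-fold. Among the falls were Axin2 (at least 5.24-fold lower, adjusted p = 0.000144) and the growth factor gene Fgf9 (log2 difference -2.87 ± 0.23). So were the potassium channel genes Kcns3 (-3.45 ± 0.35) and Kcnj8 (at least 1.68-fold lower), the rhomboid family gene Rhbdl3 (-3.32 ± 0.11) and the basement membrane gene Fras1 (-3.18 ± 0.29, well above background on 1 of the 2 arrays at 24 h). The others were Mucl1 (at least 4.92-fold lower), Rassf9 (at least 2.67-fold), the spindle orientation gene Insc (at least 2.45-fold) and the receptor gene Gpr179 (at least 1.94-fold). Normexp gave -2.62 for Kcns3, -1.41 for Fgf9, -1.23 for Fras1, -0.90 for Mucl1, -0.89 for Axin2, -0.61 for Insc, -0.49 for Rassf9, -0.46 for Gpr179 and -0.45 for Kcnj8, which alone lost its call (adjusted p = 0.0507).

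Immediate early genes rose at 24 h in 13 of 15 cases (14 adjusted over the list alone; median 0.78), with Fosl1 at 15.7-fold, Egr2 at 8.26-fold, Myc at 3.79-fold and Egr1 at 2.92-fold, and an adjusted p of 0.140 with an estimated correlation. Normexp gave 3.12 for Fosl1 and 2.32 for Egr2 on the log2 scale. The ERK list rose in 12 of 15 cases (12 adjusted over the list alone; median 1.27), with the Ets factor gene Etv4 at 11.9-fold, Dusp4 higher by 3.46 on the log2 scale and Dusp6 at 6.09-fold, and an adjusted p of 0.132 with an estimated correlation. NF-kB targets and cytokines showed 11 rises and 2 falls among 14 (the same counts adjusted over the list alone; median 0.45), with Vcam1 at 5.40-fold, Ptgs2 at 4.44-fold, Tnfaip3, a feedback inhibitor of NF-kB, at 2.82-fold and Cxcl1 at 2.80-fold. Its adjusted p with an estimated correlation was 0.152, and normexp gave 1.02 for Ptgs2 on the log2 scale. Among matrix proteases and inhibitors, 10 of 15 rose and 2 fell (11 and 3 adjusted over the list alone), with Mmp10 at 14.4-fold, Mmp3 at 8.91-fold, the collagenase gene Mmp13 at 5.04-fold and Plaur at 3.33-fold, and an adjusted p of 0.201 with an estimated correlation. Normexp gave 2.08 for Mmp3 on the log2 scale.

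ATF4 and amino acid response genes rose at 24 h in 14 of 15 cases (14 adjusted over the list alone; median 0.54), among them the stress factor gene Ddit3 (2.45-fold), the pseudokinase gene Trib3 (1.92-fold), the cystine transporter gene Slc7a11 (1.90-fold) and the mitochondrial folate enzyme gene Mthfd2 (1.80-fold). Glycolysis genes rose in 13 of 16 cases (13 adjusted over the list alone; median 0.48), including Hk2 (2.60-fold), Slc2a1 (1.83-fold), Slc16a3 (1.75-fold) and aldolase Aldoa (1.67-fold). Both lists had an adjusted p of 0.193 with an estimated correlation. Cholesterol synthesis genes rose in 6 and fell in 1 of 19 cases (the same counts adjusted over the list alone; median 0.17), including Insig1 (1.75-fold), Msmo1 (1.62-fold) and Sc5d (1.39-fold), with an adjusted p of 0.315 with an estimated correlation and the call lost in 4 of 21 alternative settings.

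Extracellular matrix genes fell in 10 of 14 cases at 24 h (10 adjusted over the list alone) and none rose, with a median of -0.47. Collagen genes Col6a2 (-1.42 ± 0.19), Col3a1 (-1.10 ± 0.06) and Col6a1 (-1.10 ± 0.07) and the collagen cross-linking oxidase Lox (-1.18 ± 0.05) fell most. Interferon response genes fell in 10 of 15 cases and rose in 1 (the same counts adjusted over the list alone; median -0.41, or -0.35 with 2 members at their bound), including the guanylate-binding protein genes Gbp3 (4.01-fold lower) and Gbp2 (-1.57 ± 0.10), Oasl2 (-0.90 ± 0.11) and Ifi44, which was at least 1.22-fold lower, while Bst2, named after its value was seen, rose by 0.32. Normexp gave -0.98 for Gbp3, -0.81 for Gbp2 and -0.15 for Ifi44, whose call was lost in 2 of 18 alternative settings. Both lists had an adjusted p of 0.152 with an estimated correlation. SRF and actin cytoskeleton genes were mixed, with 9 of 17 up and 2 down (the same counts adjusted over the list alone; median 0.44, or 0.41 with 1 member at its bound). Acta2 (2.64-fold) and Tgfb1i1 (2.08-fold) rose, while the smooth muscle genes Myl9 (-2.46 ± 0.15, normexp -1.26) and Cnn1 (-2.07 ± 0.12, normexp -1.41) fell. The adjusted p was 0.193 with an estimated correlation, and 3 of 21 alternative settings ended the call. In the Src family and focal adhesion list, 8 of 18 genes rose and 1 fell (the same counts adjusted over the list alone), with Src, Fer and integrin Itgb3 (1.32-fold) up and Tns3 down (-1.15 ± 0.08), at an adjusted p of 0.194 with an estimated correlation. Without Src, again a test chosen after the data were seen, 7 of 17 rose and 1 fell, and the list did not pass (adjusted p = 0.0614, or 0.279 with an estimated correlation). G2/M cell cycle genes rose in 7 of 16 cases (7 adjusted over the list alone; median 0.15), among them Bub1 (1.35-fold), Plk1 (1.32-fold), Ube2c (1.26-fold, a call lost in 9 of 19 alternative settings) and Aurka (1.23-fold), at an adjusted p of 0.264 with an estimated correlation.

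Of 20840 genes, 4448 were higher and 4195 lower at 24 h than at 0 h (41.5% called, 51.5% of the calls higher), of which 379 and 614 differed at least 2-fold. The arrays did not overlap for 69.9% of genes, against 33.3% by chance. Under median scaling the split was 6039 higher and 2052 lower (74.6% higher), and the median log2 difference of all genes to 0 h was then 0.057 at 6 h, 0.133 at 24 h and 0.183 at 72 h, where the 75th percentile gave 0.005, -0.016 and 0.002.

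**Figure D2:**
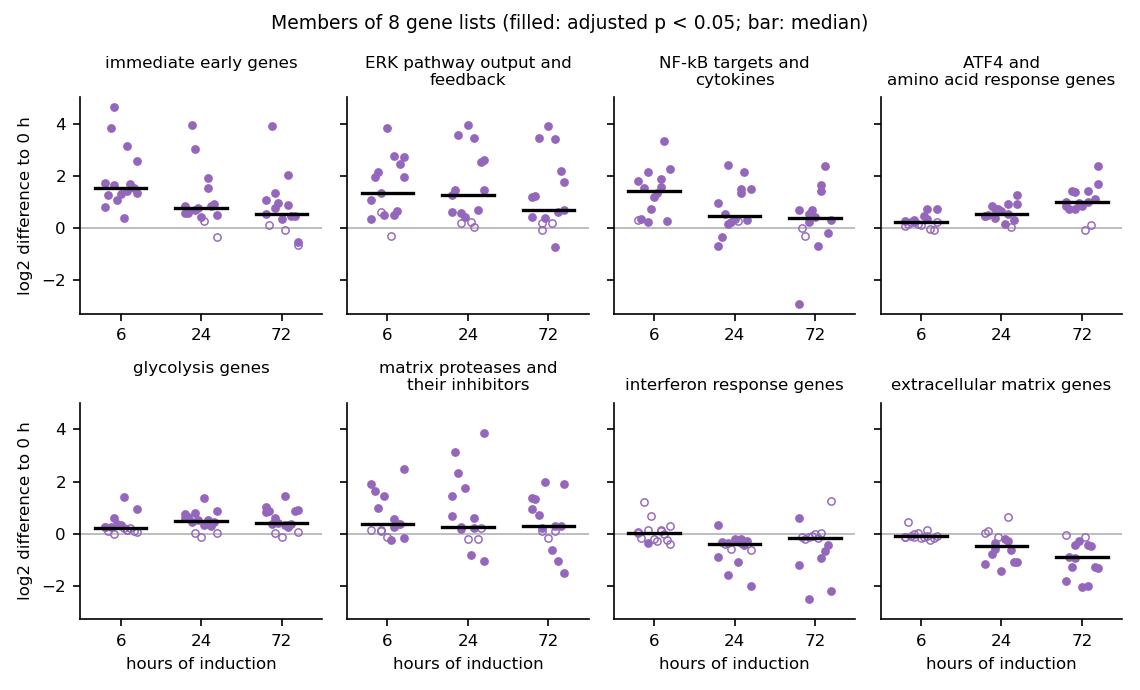
Log2 difference to 0 h (vertical axis) of each tested member of 8 gene lists at 6, 24 and 72 h (horizontal axis), filled where the adjusted p is under 0.05, with a bar at the median. Immediate early genes had medians of 1.54, 0.78 and 0.56, ATF4 genes of 0.23, 0.54 and 0.99 and matrix genes of -0.10, -0.47 and -0.91, while the interferon median changed sign at 6 h under quantile normalization (0.03 to -0.02) and at 72 h only under median scaling (-0.15 to 0.03), which moved all genes alike.

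At 72 h Ddit3 and Trib3, targets of the transcription factor ATF4, were raised. The collagen genes Col6a2 and Col3a1 and Lox, whose enzyme cross-links collagen, were lower than at 0 h, and so were Txnip, Axin2 and Fgf9. Src and the prolactin family genes were still high. ATF4 and amino acid response genes rose in 13 of 15 cases (13 adjusted over the list alone; median 0.99), with Ddit3 at 5.26-fold, Trib3 at 3.26-fold, Mthfd2 at 2.72-fold and Slc7a11 at 2.70-fold. Extracellular matrix genes fell in 12 of 14 cases (12 adjusted over the list alone; median -0.91, or -0.74 with 1 member at its bound) and none rose, with Col6a2 at -2.03 ± 0.19, Lox at -1.82 ± 0.05, Col3a1 at -1.31 ± 0.06 and the proteoglycan gene Lum at least 1.49-fold lower and well above background on 1 of the 2 arrays at 0 h. The call of Lum was lost in 5 of 18 alternative settings (adjusted p up to 0.455; -0.27 under normexp). Txnip had fallen by 4.92 ± 0.15, Rhbdl3 by 4.36 ± 0.11, Fgf9 at least 12.6-fold and Axin2 at least 5.80-fold. Normexp gave -3.47 for Rhbdl3, -1.67 for Fgf9 and -0.99 for Axin2. With an estimated correlation the adjusted p was 0.193 for the ATF4 list and 0.140 for the matrix list.

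Among the largest rises at 72 h were Prl2c5 (117.5-fold, log2 difference 6.88 ± 0.08) and Prl2c1 (at least 61.4-fold), again with an uncertain copy. The late cornified envelope genes Lce1g (at least 16.5-fold) and Lce1i (at least 8.53-fold), which belong to a family of close copies, Sprr2h (at least 23.0-fold), Serpinb2 (at least 13.8-fold), Evi2a (at least 11.1-fold), Csf2 (at least 8.61-fold), Dynap (at least 7.99-fold) and Src completed the set. Normexp kept these calls with log2 differences of 4.92 for Prl2c5, 3.87 for Prl2c1, 2.26 for Sprr2h, 2.14 for Lce1g, 2.02 for Serpinb2, 1.61 for Evi2a, 1.52 for Lce1i, 1.44 for Csf2 and 1.37 for Dynap. The remaining falls were the carbonic anhydrase gene Car3 (at least 13.0-fold), the membrane protein gene Tmem255a (at least 18.6-fold), the Nogo receptor relative Rtn4rl1 (at least 17.4-fold), the secreted factor gene Ecrg4 (at least 6.25-fold) and Mucl1 (at least 5.44-fold). Chrdl2, a relative of the BMP antagonist chordin, was at least 10.4-fold lower by the mean of its 2 arrays at 0 h, although these differed widely (SD 2.0 on the log2 scale). Its call was lost in 1 of 18 alternative settings. Normexp gave -1.99 for Tmem255a, -1.97 for Rtn4rl1, -1.64 for Car3, -1.56 for Chrdl2, -1.15 for Ecrg4 and -0.89 for Mucl1, all still called.

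Immediate early genes rose in 11 of 15 cases at 72 h and fell in 1 (11 and 2 adjusted over the list alone; median 0.56), led by Fosl1 (15.2-fold), Myc (4.13-fold), Egr2 (2.56-fold) and Atf3 (2.10-fold). The ERK list rose in 11 and fell in 1 of 15 cases (the same counts adjusted over the list alone; median 0.70), led by Etv4 (10.9-fold), Dusp4 (10.6-fold) and Etv5 (4.55-fold). Their adjusted p with an estimated correlation was 0.193 and 0.152, and normexp gave 3.08 for Fosl1 on the log2 scale. Glycolysis genes rose in 13 of 16 cases (13 rose and 1 fell adjusted over the list alone; median 0.40), with Hk2 at 2.70-fold, Aldoa at 2.03-fold, Slc2a1 at 1.86-fold and phosphofructokinase Pfkl at 1.86-fold, at an adjusted p of 0.194 with an estimated correlation. Among p53 targets 11 of 16 rose and 4 fell (11 and 5 adjusted over the list alone; median 0.53), and the list only just passed (camera adjusted p = 0.0489), a call lost in 13 of 21 alternative settings. Cdkn1a (3.39-fold) and Plk2 (2.65-fold) rose, while Sesn1 (-1.69 ± 0.07) and the antiproliferative gene Btg2 (-1.38 ± 0.10) fell, at an adjusted p of 0.212 with an estimated correlation. G2/M genes rose in 8 of 16 cases (8 adjusted over the list alone; median 0.16), led by Bub1 (1.51-fold), Ube2c (1.49-fold), Cenpe (1.29-fold) and Aurka (1.20-fold), at an adjusted p of 0.315 with an estimated correlation and with the call lost in 3 of 21 alternative settings.

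At 72 h 5718 genes were higher and 5123 lower than at 0 h (52% called, 52.7% of the calls higher), and 605 and 1036 of them differed at least 2-fold. The arrays did not overlap for 78.1% of genes, against 33.3% by chance. Median scaling gave 8017 higher and 2664 lower (75.1% higher).

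**Figure D3:**
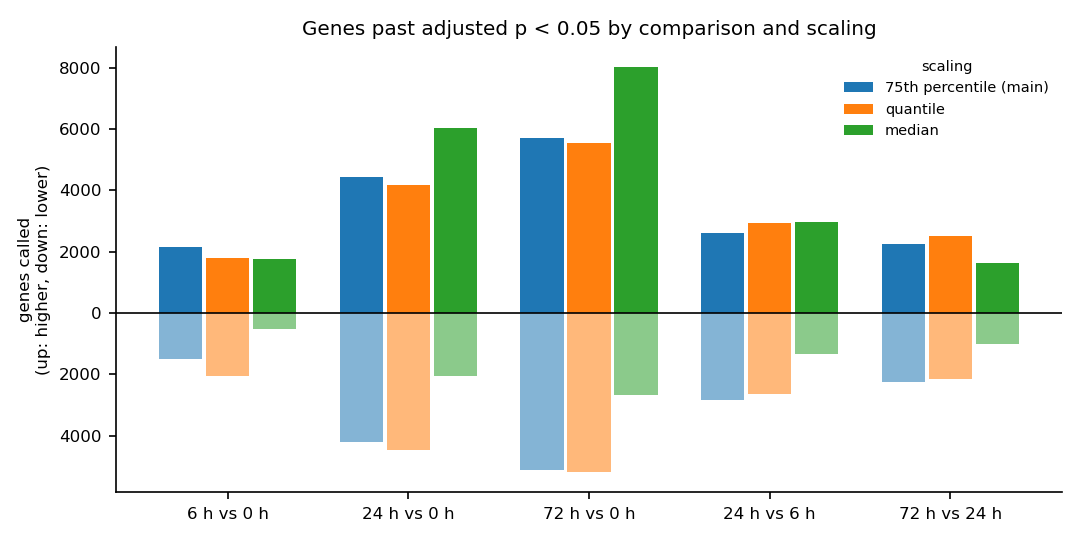
Number of genes past an adjusted p of 0.05 (vertical axis; bars up for higher, bars down for lower) in 5 comparisons between times (horizontal axis) under 3 scalings. With the 75th percentile 5718 genes were higher and 5123 lower at 72 h than at 0 h, and with the median 8017 and 2664.

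Between 6 h and 24 h, Prl2c5 rose a further 14.7-fold (log2 difference 3.88 ± 0.08), while Dynap (at least 9.18-fold) and Lce1g (at least 6.65-fold) rose from a level not well above background. The doubtful features of Efcab1 (at least 17.7-fold) and Rpl10l (at least 14.0-fold) were also higher at 24 h than at 6 h. Robo4, a guidance receptor known from endothelium, was at least 8.79-fold lower at 24 h than at 6 h, Mucl1 at least 2.78-fold and Rassf9 at least 2.64-fold, and Car3 fell by 2.77 ± 0.37 and was well above background on 1 of the 2 arrays at 24 h. Nostrin, a regulator of nitric oxide synthase, was at least 5.11-fold lower by the mean of its 6 h arrays. These had an SD of 2.18, so the fold need not hold for each array, and the call was lost in 9 of 18 alternative settings. Normexp gave 1.83 for Efcab1, 1.68 for Rpl10l, 1.20 for Dynap and 1.02 for Lce1g, and -1.37 for Car3, -1.20 for Robo4, -1.18 for Nostrin, -0.57 for Mucl1 and -0.54 for Rassf9. In this step 2621 genes rose and 2831 fell, and under median scaling 69% of the calls were higher against 48.1% here. Without 6 h replicate 1, 6 h replicate 2 or 24 h replicate 2, the total of 5452 dropped to 2621, 2649 and 3389.

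Between 24 h and 72 h, Lce1g rose 3.27-fold (1.71 ± 0.25), the lipid droplet gene Plin4 3.26-fold (1.71 ± 0.28), the immune receptor gene Lilrb4a at least 2.98-fold, the keratin gene Krt78 at least 1.85-fold and Cibar2 at least 1.33-fold. Ivl was at least 6.39-fold lower at 72 h than at 24 h, Tmem255a at least 5.90-fold and the elastic fibre gene Fbln5 at least 3.42-fold, and the features of Efcab1 (at least 15.4-fold) and Rpl10l (at least 12.2-fold) returned to background. Of 18 alternative settings, 5 each ended the calls of Krt78 (adjusted p up to 0.112) and Cibar2, 4 that of Plin4, 3 each those of Lilrb4a and Fbln5 and 1 that of Lce1g. Normexp gave a 2.1-fold rise for Lce1g and log2 differences of 0.78 for Plin4, 0.35 for Lilrb4a, 0.34 for Krt78 and 0.25 for Cibar2. The falls were then -1.95 for Efcab1, -1.76 for Rpl10l, -0.95 for Ivl, -0.92 for Tmem255a and -0.49 for Fbln5. Here 2248 genes rose and 2259 fell, with 61.8% of the calls higher under median scaling against 49.9%. The total of 4507 dropped to 1913, 1084 and 1470 without 24 h replicate 1, 72 h replicate 1 and 72 h replicate 2.

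Genes that had changed by 24 h were also called at 72 h in most cases, Fosl1, Prl2c5, Axin2 and Rhbdl3 among them. The same direction was called at both times for 7034 genes, 3666 up and 3368 down, or 81.4% of the genes called at 24 h, and 140 genes were called in opposite directions. Independent lists of these sizes would share 1220 rising and 1031 falling genes. In 100 simulations of unchanged groups against the same controls 0 genes were shared by 24 h and 72 h, but such groups give almost no calls, so this count says nothing about the shared controls. The log2 differences of all genes correlated between 24 h and 72 h at 0.84, between 6 h and 24 h at 0.65 and between 6 h and 72 h at 0.51, where the simulations gave 0.50 for each. Their covariances were 0.295, 0.127 and 0.12 against 0.0144 simulated. Of the 6 h calls, 2908 (79.6%) were called the same way at 24 h and 2557 (70%) at 72 h. The comparisons share the 2 arrays at 0 h, too few to give each of a pair 2 of its own, so part of the excess of shared calls may come from the shared controls. With 1 array at 0 h for each of a pair, in both assignments, the correlations were 0.75 and 0.73 between 24 h and 72 h, 0.50 and 0.49 between 6 h and 24 h and 0.40 and 0.37 between 6 h and 72 h. The covariances were then 0.276 and 0.272, 0.106 and 0.107, and 0.101 and 0.0975.

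YAP/TEAD targets moved both ways at every time and did not pass the list test (adjusted p = 0.131, 0.572 and 0.405 at 6, 24 and 72 h). At 6 h 8 of 22 rose and 5 fell, at 24 h 11 and 9, and at 72 h 10 and 7 (9 and 5, 11 and 9, and 10 and 7 adjusted over the list alone). Oxidative phosphorylation genes had medians of 0.06, 0.09 and 0.07, which changed sign under quantile normalization (-0.02, -0.01 and -0.04), and 2, 2 and 5 of 16 rose while 0, 1 and 1 fell (list test adjusted p = 0.131, 0.0835 and 0.131; 1, 2 and 5 rose and 0, 0 and 1 fell adjusted over the list alone). Some lists called at another time did not pass. At 6 h these were extracellular matrix (adjusted p = 0.115, 0 of 14 called), cholesterol synthesis (0.412) and interferon response genes (0.462). At 24 h they were p53 (0.0549, passed in 5 of 21 alternative settings), STAT3 (0.329) and TGF-beta targets (0.726), DNA replication (0.235) and heat shock genes (0.131) and fibroblast and mesenchymal markers (0.131). At 72 h they were NF-kB (0.0608), interferon (0.0614), SRF and actin (0.0767) and matrix protease genes (0.0776), fibroblast and mesenchymal markers (0.228), heat shock (0.318) and DNA replication genes (0.383). Of 21 alternative settings, the interferon list passed at 72 h in 8 and the NF-kB, SRF and actin and matrix protease lists in 3 each. For each of these lists, and for p53 targets at 24 h, the settings passed include fry, which asks only whether members change at all. Others at 72 h were Src family and focal adhesion (0.412), STAT3 (0.797), TGF-beta (0.932) and cholesterol synthesis genes (0.979). For TGF-beta targets at 24 h the median was -0.14 and the mean 0.26, and for fibroblast and mesenchymal markers at 72 h the median was 0.39 and the mean -0.05, with 8 of 12 members up and 4 down.

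Of 6 tested epithelial markers, 0 were called at 6 h, and at 72 h 2 rose and 2 fell (0 called, and 2 and 2, adjusted over the list alone; list test adjusted p = 0.405 at 6 h, 0.916 at 24 h and 0.979 at 72 h). The genes named here were chosen after their values were seen. At 72 h the keratin genes Krt8 (1.90-fold) and Krt18 (1.27-fold) rose and Krt14 (-1.93 ± 0.14) and Krt19 (-1.46 ± 0.33) fell. The macrophage, endothelial, skeletal muscle and adipocyte lists had fewer than 5 tested members (4, 3, 3 and 4) and were not tested as lists. Of the 4 macrophage markers 2 rose at 6 h, 3 at 24 h and 2 at 72 h, and 0 fell (the same counts adjusted over the list alone; medians 0.53, 0.56 and 0.33, or 0.13, 0.41 and 0.33 with Cd68 at its bound). Csf1r rose by 0.88, 0.81 and 0.44 at the 3 times, Cd68, from a level not well above background, by at least 0.05, 0.51 and 1.55, and Cd14 by 0.30 at 24 h, while Fcer1g gave 0.08, 0.01 and -0.02. At 72 h the endothelial receptor gene Tek fell to a level not well above background (log2 bound -1.44), while Kdr (-0.02 ± 0.06) and Pecam1 (0.04 ± 0.08) did not pass. Skeletal muscle actin Acta1 rose 2.76-fold and troponin Tnnt1 fell by 2.43 ± 0.21, with Des at 0.10 ± 0.05. In the adipocyte list Fabp4 rose 3.76-fold, and Lpl (-1.41 ± 0.06), Cebpa (-1.37 ± 0.15) and Pparg (-0.45 ± 0.06) fell.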

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

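The tests of keratinocyte genes, of a transcript shared by Sprr2 probes, of single-feature defects, of other probes and of chaperones were chosen only after the result was seen. Some genes were called in opposite directions against 0 h at different times. The direct test between those times then passed as well (limma adjusted p under the threshold). For single genes this is no further support, since the direct difference sums both opposite effects. Between 6 h and 72 h this held for 210 genes that were first higher and then lower and for 116 first lower and then higher. The next 3 genes were not well above background at 1 of the times compared, so their differences are bounds against the background limit. Ivl was called higher at 6 h and 24 h and lower at 72 h (bounds -2.67 from 24 h to 72 h and -4.20 from 6 h to 72 h). Tada2b was lower at 6 h and higher later (bounds 1.07 from 6 h to 24 h and 1.68 to 72 h), and Robo4 was higher at 6 h and lower later (bounds -3.13 and -3.29). Fos differed by -1.06 from 24 h to 72 h and -3.13 from 6 h to 72 h. Rrm2 differed by -0.62 and -0.65 over the same spans, Itgb3 by -1.34 and -1.42, and Cdc6 by -0.47 from 6 h to 72 h. Fas differed by -1.16 from 6 h to 24 h and by 0.37 from 24 h to 72 h. Btg2 differed by -1.45 from 6 h to 24 h and -2.12 from 6 h to 72 h. The G2/M list was called lower at 6 h and higher later. Its direct median to 24 h was 0.27 (12 of 16 genes rose, camera adjusted p = 5.92e-06, 0.190 with an estimated correlation). To 72 h it was 0.30 (13 of 16 rose, camera adjusted p = 0.000476, 0.261 with an estimated correlation). Direct list tests are given only where a list had opposite calls, and they sum both effects, so they are no further support either.

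Of 14 tested cornified envelope genes 7 were called higher at 6 h, 9 at 24 h and 5 at 72 h, and 0, 0 and 3 lower (Ivl, Sprr2f and Sprr2g at 72 h). This set, the tested Sprr and Lce genes and Ivl, was formed after some of its members were seen among the largest rises. It includes those members and close copies, and was not tested as a list. The other tested keratinocyte genes had a median of -0.36 at 24 h (10 tested, 1 higher, 6 lower; Krt14 -1.33). This argues against a growing share of cells that express them. Keratinocytes present from the start stayed open, since the test reads only changes from 0 h. At 0 h the mean log2 signals, relative to the percentile used for scaling, were 2.7 for Krt15 and 2.04 for Trp63. Those of the others lay between -4.26 and -0.09. A transcript read by the probes of all the Sprr2 genes that rose was argued against by the span of their differences between 6 h and 72 h, 3.70 ± 0.20 over 5 genes well above background at each time, from 1.40 for Sprr2h to -2.30 for Sprr2g, while sharing among fewer of them stayed open. Activation of the whole chromosome stretch stayed open, since only 1 other gene of it, Crct1, was tested (1.19 at 24 h). Higher c-Src, named by the design, may account for the rise and was not tested apart from doxycycline and time.

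Efcab1 and Rpl10l were bright at 24 h alone, on both arrays. Defects that strike single features by chance stayed open: 2 features were this bright, against 1.09 expected at a log2 margin of 3 and 0.0394 at a margin of 5, which was set after the margins of the 2 (5.52 and 5.22) were seen. A rise read by all probes was argued against, since 0 of the 3 other probes of these genes were well above background on both 24 h arrays, although 1 other Efcab1 probe was bright on 24 h replicate 1 (-1.06, against -6.57 on replicate 2). A defect shared by neighbouring features cannot be told apart from a rise of single transcript forms: the median over the 8 features around each, 16 in all with some shared, was 0.48, between the bounds of 0.2 and 0.5 set beforehand, and 1 of them was higher by 3.19. With 1 more column on each side (26 features), a wider set than the one written beforehand, the median was 0.15. The 2 features lie in rows 8 and 10 of column 41, where 0.0388% of other features lie as near, so they may share such a defect.

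ATF4 and amino acid response genes were called higher in 7, 14 and 13 of 15 cases at 6, 24 and 72 h, with medians of 0.23, 0.54 and 0.99. With the estimated correlation of 0.305 the list's adjusted p by camera was 0.259, 0.193 and 0.193, so none of the 3 calls held. Endoplasmic reticulum stress of a kind that raises chaperones was argued against as the cause by these genes, whose median at 72 h was -0.23 (8 tested, 0 higher, 5 lower). Such stress acting on ATF4 without a rise of these chaperones was not tested and stayed open. Doxycycline itself may be the cause and stayed open, since 0 of the 8 arrays came from cells without the c-Src vector.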

How the results depend on the processing

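All alternatives were planned except 1, the Src family list without Src, which was chosen after the data were seen and gave adjusted p of 0.0195, 0.0614 and 0.725 at 6, 24 and 72 h, which lost the 24 h call, and 0.219, 0.279 and 0.81 with an estimated correlation, which lost the 6 h call as well. Src stayed called in all 57 tests of its level, and of 3941 values of named genes 3747 kept their side of the threshold (3 of them, all Fer between 24 h and 72 h and never called, with a change of sign), 193 lost the call, 1 gained it and 0 reversed. Of 1326 list tests 1206 kept their side (17 with a change of sign and no call), 77 lost it and 43 gained it, and of 249 counts 202 stayed within 1.5 times. Median scaling left 526, 2052 and 2664 genes lower at 6, 24 and 72 h and 2625 different between 24 h and 72 h. Without a filter on dim probes 648 genes were higher and 223 lower at 6 h, 2937 and 2661 at 24 h, 2044 differed between 6 h and 24 h and 928 between 24 h and 72 h, 4567 were shared by 24 h and 72 h, and 12 lists passed at 72 h. The mean of a gene's probes gave 11 lists at 72 h. Fitting the groups compared alone, with fewer arrays, gave 1095 higher and 718 lower at 6 h, 2672 between 6 h and 24 h and 1069 between 24 h and 72 h. With an estimated correlation between genes 0, 0 and 0 lists passed at 6, 24 and 72 h, and fry gave 19 at 24 h and 19 at 72 h. The fry test asks whether members change at all, whereas camera asks whether they change more than other genes. With 41.5% and 52% of all genes called at 24 h and 72 h, many lists can pass fry. Of the 43 list tests that gained the call, 22 were of fry. Asking for 2-fold as well left 181 higher and 45 lower at 6 h, 379 and 614 at 24 h, 605 and 1036 at 72 h, and 476 and 293 between the later times. An adjusted p under 0.1 gave 2444 lower at 6 h. Leaving out each array gave 801 to 2093 higher and 414 to 1499 lower at 6 h, 2621 to 4652 between 6 h and 24 h and 1084 to 3914 between 24 h and 72 h. Higher counts at 6 h were 986, 1065 and 1023 without 0 h replicate 1, 0 h replicate 2 and 6 h replicate 1, with 801 without 6 h replicate 2, and lower counts 628, 503, 498 and 414, with 978 without either 72 h array. Between 6 h and 24 h 2621, 2649 and 3389 remained without 6 h replicate 1, 6 h replicate 2 and 24 h replicate 2, and between 24 h and 72 h 1913, 1084 and 1470 without 24 h replicate 1, 72 h replicate 1 and 72 h replicate 2. A lone array was assumed to vary like the other groups. The cause was not tested for the other settings. A block on replicate number gave 2407 higher and 1661 lower at 6 h and changed no count by over 1.5 times, with 14 lists at 6 h and 6 at 72 h, where DNA replication genes (adjusted p = 0.051) and p53 targets (0.065) did not pass. A block on slide or scan was not run, as there was 1 of each, and signal over background limits genes near the floor.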

Other observations

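The genes in this part were chosen after their values were seen, and the test of beta-catenin targets was chosen before its result was seen. No list of them was fixed or tested. Among genes of ligands of the EGF receptor family, Ereg (8.35-fold at 6 h, 6.65-fold at 24 h and 5.30-fold at 72 h) and Hbegf (4.49-fold, 3.57-fold and 2.58-fold) rose. Nrg1 rose by 0.68 at 24 h and 1.30 at 72 h on the log2 scale, Tgfa at least 1.76-fold at 24 h and 1.75-fold at 72 h, with neither called at 6 h, whereas Epgn was at least 1.99-fold lower at 24 h. The chromatin protein genes Hmga2 (1.81, 3.52 and 3.21 on the log2 scale) and Hmga1 (0.38, 1.54 and 1.61) rose at each time, as did the metallothionein genes Mt1 (0.69, 1.12 and 1.42 on the log2 scale) and Mt2 (0.66, 1.24 and 1.62). At 72 h the cytokine genes Cxcl12 (-1.83), Il33 (-2.20) and Il18 (-2.19) fell, while Il11 (0.81) and Ccl2 (0.71) rose. The keratin genes Krt15 (-3.30), Krt7 (-2.58) and Krt14 (-1.93) fell, while Krt8 (0.93) and Krt18 (0.34) rose.

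Several genes of Wnt signalling, chosen after their values were seen and not tested as a list, were called lower. At 72 h Axin2 was at least 5.80-fold lower, Wnt10a at least 2.63-fold, and Nkd1 (-2.20), Wnt5a (-1.85), Lef1 (-1.17), Wnt10b (-0.98) and Notum (-0.64) fell. The hypothesis of lower output of beta-catenin was tested on target genes not looked at before. Their median at 72 h was -0.39 over 3 tested genes, Znrf3, Apcdd1 and Bmp4, of which 1 was called lower. These are too few to decide, so lower output of beta-catenin may or may not account for the falls.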
